A study of Mus musculus with 9 samples.

How the data were processed

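Gene expression was measured in the limbic area of the brain of male ICR mice (an outbred laboratory stock) on Affymetrix GeneChip MG-430 PM arrays, with 1 array per sample and 9 arrays in all. Per the labels' protocols, total RNA was extracted with Trizol, amplified and biotin-labelled with the manufacturer's 3' in vitro transcription kit, hybridised and scanned. The deposited values are linear probe set intensity values, made with Affymetrix Expression Console per the submitters' processing notes. The summarisation algorithm and the version of that program are not given in the sources used here. In the deposited table, 43.5% of probe sets held a value that 2 or more arrays shared exactly, and the array medians lay between 13.7 and 14.4, so the intensities were used as already normalised between arrays.

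The deposited values covered 45141 probe sets, of which 104 were control probe sets. Gene names came from the platform annotation: 28898 probe sets had 1 gene symbol, 551 had several and 15692 had no name in that annotation. Of the named ones, 28689 matched a gene ID in the RefSeq gene table of assembly GRCm38.p6, which was used for names only. Intensities were raised to a floor at percentile 5 of all values (an intensity of 4.63) and converted to log2. A gene was represented by the single-symbol probe set of highest mean over the 9 arrays, which gave 17097 genes, of which 7180 had several probe sets. Genes below percentile 40 of the mean log2 value (3.90, an intensity of 14.9) were left out, which removed 6839 genes and left 10258 for testing. Probe sets without a name or with several symbols entered no gene test. In a separate fit of 27022 probe sets by the same limma settings, which included 7820 without a single symbol, 0 were called in each of the 3 comparisons, while 21, 54 and 33 of the unnamed ones reached an unadjusted p under 0.05 with at least a 1.5-fold difference.

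The labels assigned 3 arrays each to water, imipramine and Aurantiochytrium 18W-13a, called Aurantiochytrium from here on. One linear model with a mean per group was fitted to all 9 arrays with limma 3.58.1 (lmFit and eBayes with the default prior) in R 4.3.3, after reading the values with version 1.17.8 of the data.table package. This design leaves 6 residual degrees of freedom per gene. The comparisons were imipramine minus water, Aurantiochytrium minus water and Aurantiochytrium minus imipramine. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes of a comparison, and a gene was called at an adjusted p under 0.05. As a description, genes with an unadjusted p under 0.05 and at least a 1.5-fold difference were also counted.

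Before the data were examined, 48 gene lists were fixed, 28 of processes and 20 of cell types and neighbouring brain regions. Of their 1064 genes, 929 were named in the probe annotation. The 46 lists with at least 5 tested genes were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. A list was called at an adjusted p under 0.05. The camera test asks whether a list's genes differ from the other genes. It was repeated with a correlation estimated for each list, and limma's fry, which asks whether the genes of a list move on balance in a single direction, was run beside it. The score of a list on an array is the mean, over its tested genes, of the deviation of the log2 value from that gene's mean over the 9 arrays.

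The rule for the genes named was also fixed then. For each comparison with water it takes the 8 genes each way that were called with the largest log2 difference. Where fewer were called it fills the list with the genes of smallest unadjusted p whose treated arrays all lie on the same side of all water arrays. It adds up to 4 members of each called list with the smallest unadjusted p in the list's direction, and a fixed set of genes of interest. For Aurantiochytrium minus imipramine it takes 5 each way. Of the fixed set, Dcx and Htr2a were among the genes with no single-symbol probe set in the annotation used, and Slc6a4, Aif1, Il1b, Tnf and Hmgcs1 lay below the filter on dim genes. Some genes of the fixed set are not reported here.

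The fit was tested on simulated data for imipramine minus water over 10258 genes, of which 200 were changed. With the noise of all 9 arrays, 45% of the genes changed by a log2 of 1 and 78% of those changed by a log2 of 2 were called, with 12 unchanged genes called. With the noise of the 8 arrays without imipramine replicate 2, these shares were 56% and 91%, with 5 unchanged genes called. In both runs the shifted list was called and 0 of 19 unshifted lists were called by camera. Each gene was drawn independently, with the same spread on every array. These runs therefore do not test camera where genes of a list vary together. In the 8 real arrays without imipramine replicate 2, striatal neuron markers varied together within groups at a mean correlation of 0.353. The runs also leave out the RNA quality differences of the real arrays, so real recovery may differ.

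Array quality was read from the control probe sets: the 3' over 5' signal of the Gapdh and Actb transcripts, and the bacterial poly-A control transcripts (Dap, Thr, Phe, Lys) that are added to RNA before amplification. The labels name no batch. A signal of the 3' Dap probe set above an intensity of 30 marked arrays with poly-A control signal, and this split was used as a technical batch. Its fit as a block, and the fit of the 6 arrays with that signal, were added after the data were examined, as were 2 fits with the log2 Gapdh ratio as a covariate, on all 9 arrays and on the 8 without imipramine replicate 2.

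Alternatives fixed beforehand were quantile normalisation and median centring of the log2 values, no filter or a filter at percentile 60, averaging of probe sets, a trended and robust prior, array weights, a fit of only the 2 groups compared, the replicate number as a block, a higher floor at percentile 20, and leaving out each array in turn. To judge the covariance between the comparisons with water, 100 sets of unchanged groups were simulated with the residual spread of each gene, and 100 more were fitted with limma to count the genes both comparisons share. In 100 further sets, arrays of equal number shared a part of their noise, taken as the residual variance that the replicate block removes. For both comparisons with water, the deviations from the group means of all 3 pairs of arrays of equal number were correlated above 0.1 (0.438 to 0.791 with imipramine, 0.103 to 0.780 with Aurantiochytrium). By that check, which comes from the data and not from the labels and was read by comparison only after the fits were seen, the numbers were treated as a possible pairing. Numbers that pair both treatments with water would also pair the treatments, where 1 of 3 pairs passed the limit. The pairing is therefore not established, and the main fits do not use it. Correlations over arrays were tested by exact permutation. Splits of 6 arrays into 3 and 3 were all refitted, which gives 10 splits and no share under 0.1. Random lists (10000 draws) were matched on mean expression. The 9 value columns were all used. The number of arrays limits the precision, and arrays give no count depth.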

Results

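Transcript levels were measured in the limbic area of the brain of male ICR mice after 14 days of daily oral gavage, with 3 arrays each for water, imipramine and Aurantiochytrium 18W-13a. Imipramine, a tricyclic antidepressant that blocks reuptake of serotonin and noradrenaline, was given at 20 mg/kg as the positive control. Aurantiochytrium is a genus of lipid-rich marine microorganisms, and the genus name alone stands for strain 18W-13a from here on. The dose of its preparation is not given in the sources used here. The design asks which limbic transcripts differ from the vehicle group with either treatment. After filtering, 10258 genes were compared. The median standard error of a log2 difference was 0.23, and the number of arrays limits this precision. The labels do not say that the 3 samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

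The arrays differed in RNA quality and in library preparation in ways that cut across the groups. The 3' over 5' signal of the Gapdh control, which increases when RNA is degraded, was 7.55 on imipramine replicate 2 and between 0.944 and 2.19 on the other 8 arrays. For Actb it was 6.16 against 1.81 to 3.53. The first principal component held 72.9% of the variance and followed the log2 Gapdh ratio over the 9 arrays (Pearson's r = 0.994, exact permutation p = 8.27e-05, adjusted 0.000248; Spearman's rho = 0.967, exact permutation p = 0.000165, adjusted 0.000496). Without the 2 arrays farthest from the median ratio, r was 0.977. In the 8 arrays without imipramine replicate 2, the first component held 51.4% and followed the ratio as closely, with the sign of a component being arbitrary (r = -0.976, exact permutation p = 0.000446, adjusted 0.000670; rho = -0.952, exact permutation p = 0.00114, adjusted 0.00171; r = -0.985 without the 2 farthest). The poly-A control transcript Dap gave intensities of 85.0 to 462 on replicates 1 and 2 of each group. It gave 8.42 to 10.6 on replicate 3 of each group, so each group held 2 arrays with these controls and 1 without. The 3 arrays without the controls also had the lowest Gapdh ratios (0.944 to 1.04), so differences between the 2 batches may also reflect RNA quality. Over the 6 arrays with the controls, the Gapdh ratio followed the first component at r = 0.991 (exact permutation p = 0.00972, adjusted 0.00972; 0.987 without the 2 farthest) and rho = 0.943 (exact permutation p = 0.0167, adjusted 0.0167). The adjustment covers these 3 relations, and 3 arrays without them are too few for a correlation. No pair of arrays was identical. The highest correlation between arrays was 0.996, between different groups, and 0.989 within a group.

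**Figure D1:**
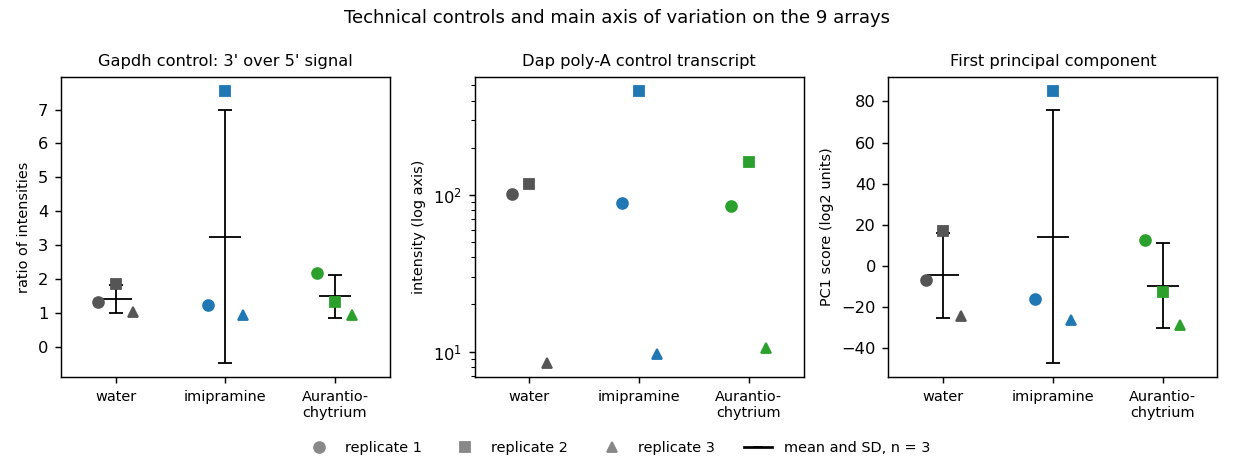
Gapdh 3' over 5' ratio of intensities, intensity of the Dap poly-A control (log axis) and score on the first principal component (log2 units) for each array. Points are arrays and symbols are replicate numbers. Lines give the mean and SD of 3 arrays, except in the Dap panel, which shows points only. Imipramine replicate 2 lies apart at a ratio of 7.55 against at most 2.19 elsewhere, and replicate 3 of each group has Dap intensities of 8.42 to 10.6 against at least 85.0 elsewhere.

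With Aurantiochytrium, the genes ranked by unadjusted p against water included genes of dopamine neurons and of the thalamus on the lower side, and genes of striatal neurons and an activity-induced transcription factor on the higher side. Slc6a3, the plasma membrane dopamine transporter, had a log2 intensity of 3.78 ± 0.03 (SD, n = 3) against 6.15 ± 0.56 in water, a log2 difference of -2.37 ± 0.35 (SE). All 3 Aurantiochytrium arrays lay below the filter level of 3.90, where signal is not shown to be above background, and with that group set at this level the difference was -2.25. Ppp1r1b, a dopamine- and cAMP-regulated phosphoprotein of striatal medium spiny neurons, was at 7.96 ± 0.53 against 5.70 ± 0.98, a difference of 2.26 ± 0.56. Npas4, a transcription factor induced by neuronal activity, was at 5.39 ± 0.69 against 3.90 ± 0.15, a difference of 1.49 ± 0.38. Its water replicates 2 and 3, at 3.85 and 3.78, lay below the filter level. None of these genes passed the adjustment over all genes. Limma called 0 of 10258 genes, with a smallest adjusted p of 1.00, while 136 genes (96 higher, 40 lower) had an unadjusted p under 0.05, where 512.9 are expected by chance.

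Of the genes whose 3 Aurantiochytrium arrays all lay on the same side of the 3 water arrays, those of smallest unadjusted p on the lower side were, after Slc6a3, Aldh1a1, a retinaldehyde dehydrogenase of a subset of midbrain dopamine neurons (-1.80 ± 0.34), and Slc17a6, a vesicular glutamate transporter of subcortical neurons (-1.51 ± 0.30). They were followed by the homeobox gene Shox2 (-1.63 ± 0.42), the aromatic amino acid decarboxylase Ddc (-2.25 ± 0.58), the calsyntenin Clstn2 (-0.72 ± 0.21), the Wnt pathway factor Tcf7l2 (-1.59 ± 0.51) and the synaptic scaffold gene Tanc1 (-0.72 ± 0.24). On the higher side were Spry2, an inhibitor of receptor tyrosine kinase signalling (0.66 ± 0.12), Cdc42ep3 (0.83 ± 0.18), the actin-binding gene Actn2 (1.18 ± 0.26), Ppp1r1b, Spata13 (0.99 ± 0.25), Npas4, the metalloproteinase gene Adamts3 (1.03 ± 0.27) and the striatal small GTPase Rasd2 (1.53 ± 0.40). Both probe sets of Slc17a6 gave negative differences (-1.70 and -1.51), while a second probe set gave 0.74 for Rasd2, 0.43 for Cdc42ep3 and -0.46 for Clstn2. Of the 27 named genes with several probe sets above the filter, 19 had one that differed by more than 1.5 times and 4 one of the other sign. Groups did not overlap for 7.17% of genes, against a chance share of 10%. With weights per array, limma called 3 genes: Aldh1a1 (-1.65 ± 0.14, adjusted p = 0.0105, range 0.0105 to 1.00 over 23 alternatives), Slc6a3 (-2.17 ± 0.22, adjusted p = 0.0195, range 0.0195 to 1.00 over 22) and Actn2 (1.43 ± 0.17, adjusted p = 0.0452, range 0.0452 to 1.00 over 22). Those weights were 0.0848 for imipramine replicate 2 and 5.95 for Aurantiochytrium replicate 2.

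Counted at an unadjusted p under 0.05 and at least 1.5-fold, 74 genes differed between Aurantiochytrium and water (50 higher, 24 lower). The count was 174 (132 higher, 42 lower) without imipramine replicate 2, which changes only the shared error estimate here, 49 without water replicate 2 and 37 without Aurantiochytrium replicate 2. It was 80 with the poly-A control batch as a block and 69 within the 6 arrays with these controls, and the arrays without them are 1 per group. Without imipramine replicate 2 limma still called 0 genes, with 424 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0901.

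**Figure D2:**
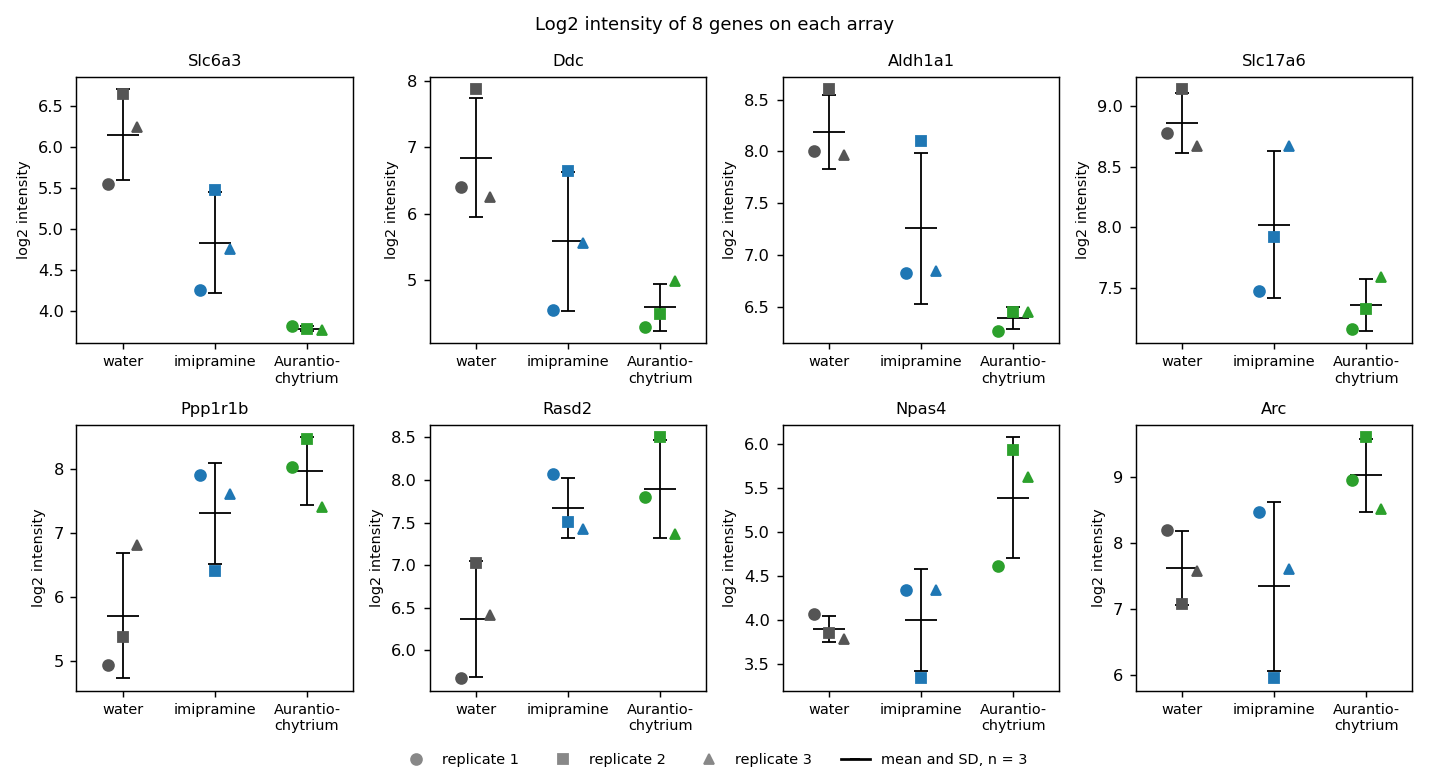
Log2 intensity of 8 genes on each of the 9 arrays, with points for arrays, symbols for replicate numbers and lines for the mean and SD of 3 arrays per group. Slc6a3 was at 3.78 ± 0.03 with Aurantiochytrium against 6.15 ± 0.56 with water, and Ppp1r1b at 7.96 ± 0.53 against 5.70 ± 0.98.

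Among the gene lists, 11 of 46 were called by camera for Aurantiochytrium against water (6 higher, 5 lower), and 0 by camera with an estimated correlation (8 lists at unadjusted p under 0.05, smallest adjusted p 0.123) or by fry (3 lists at unadjusted p under 0.05, smallest adjusted p 0.337). Markers of striatal medium spiny neurons rose together: 15 of 15 were higher, with a mean log2 difference of 1.24 and an SD over the genes of 0.59 (camera, adjusted p = 2.34e-21; adjusted p = 0.123 with an estimated correlation). Of these, 9 had an unadjusted p under 0.05, 5 passed when adjusted over the list alone and 0 passed over all genes. Beside Ppp1r1b and Rasd2, the forkhead gene Foxp1 (0.93 ± 0.27) and the sodium channel subunit Scn4b (0.92 ± 0.29) led the list by unadjusted p, with differences below the list's mean. All 7 Foxp1 probe sets gave 0.80 to 1.04. Scn4b was at 0.60 without water replicate 1. The list's scores did not overlap between the groups (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). The mean was 1.55 in the arrays with poly-A controls and 0.62 in the pair without them, and with this batch as a block the adjusted p was 1.05e-20.

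Immediate early genes, which neurons transcribe within minutes of activity, rose as a list: 22 of 23 were higher, with a mean of 0.67 (camera, adjusted p = 1.61e-16; adjusted p = 0.151 with an estimated correlation). Npas4, Fosb (0.64 ± 0.20), Junb (0.98 ± 0.34) and Egr2 (1.59 ± 0.63) had an unadjusted p under 0.05, and 0 of the 23 passed when adjusted over the list alone or over all genes. Arc, a cytoskeletal regulator of synapses, differed by 1.41 ± 0.61, Egr1 by 0.66 ± 0.63 and Fos by 0.40 ± 0.97, the last 2 by 0.43 and 0.07 without water replicate 2. Fos was at -0.02 without Aurantiochytrium replicate 3 and at 0.96 without Aurantiochytrium replicate 1. The scores did not overlap (exact permutation p = 0.1), and the mean was 0.70 with and 0.62 without poly-A controls (adjusted p = 2.23e-14 with the batch as a block). Over the 8 arrays without imipramine replicate 2, the shift of the list's score was 0.67 ± 0.18 (SE), 0.68 ± 0.17 with the log2 Gapdh ratio as a covariate, 0.35 ± 0.37 with the striatal score and 0.16 ± 0.35 with the midbrain score, and both of these regional scores differ between the groups. The signalling list of cAMP, CREB and MAPK genes rose too, with 19 of 26 higher and a mean of 0.28 (camera, adjusted p = 2.58e-05; adjusted p = 0.151 with an estimated correlation). Its leading members were the kinases Camk4 (0.85 ± 0.22, with probe sets from 0.44 to 0.86) and Rps6ka3 (0.53 ± 0.17), the adenylyl cyclase Adcy5 (0.87 ± 0.27) and the phosphodiesterase Pde1b (0.84 ± 0.35), 4 at an unadjusted p under 0.05 and 0 passing over the list alone. Adcy5 and Pde10a also stand in the striatal list, and the mean was 0.19 without these 2 genes. Within batches it was 0.34 and 0.15.

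Markers of midbrain dopamine and hindbrain serotonin neurons fell: 9 of 9 were lower, with a mean of -1.16 (camera, adjusted p = 3.18e-15; adjusted p = 0.151 with an estimated correlation). Slc6a3, Aldh1a1, Ddc and the receptor tyrosine kinase Ret (-0.39 ± 0.13, or -0.18 with the dim Aurantiochytrium group set at 3.90) had an unadjusted p under 0.05, and these 4 passed when adjusted over the list alone, against 0 over all genes. The mean was -1.30 with and -0.88 without poly-A controls (adjusted p = 8.12e-13 with the batch as a block). The serotonin neuron genes Slc6a4 and Tph2 lay below the filter on average and entered no list test. Slc6a4 was at 5.90 on water replicate 2 and 4.97 on imipramine replicate 2, against at most 3.32 elsewhere. Tph2 was at 5.95 and 5.31 on these arrays, against at most 2.87 elsewhere. Monoamine synthesis, transport and breakdown genes fell as well, with 9 of 9 lower and a mean of -0.89 (camera, adjusted p = 8.71e-09; adjusted p = 0.123 with an estimated correlation), 2 at an unadjusted p under 0.05 and the same 2, Slc6a3 and Ddc, passing over the list alone. Th, the tyrosine hydroxylase of catecholamine synthesis, differed by -2.11 ± 1.00, and by -1.36 without water replicate 2. Th, Ddc and Slc6a3 are in both lists, and without these 3 genes the midbrain mean was -0.62 and the monoamine mean -0.21. Within batches it was -0.99 and -0.67. Thalamic neuron markers fell with a mean of -0.62 and 13 of 14 lower (camera, adjusted p = 1.59e-10; adjusted p = 0.151 with an estimated correlation). By unadjusted p the list was led by Slc17a6, Tcf7l2 and Ntng1 (-0.47 ± 0.20, and -0.88 in a second probe set), with 3 at an unadjusted p under 0.05 and 1 passing over the list alone. Within batches the thalamic mean was -0.45 and -0.96, and with array weights it was -0.38. The thalamic scores overlapped between the groups, with water replicate 1 at -0.24 and Aurantiochytrium replicate 2 at -0.17. Water replicates 2 and 3 were at 0.58 and 0.60.

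Glial lists were lower by smaller amounts. Myelinating oligodendrocyte markers fell, 17 of 17 lower with a mean of -0.34 (camera, adjusted p = 1.85e-07; adjusted p = 0.151 with an estimated correlation), and Ugt8a, an enzyme of myelin lipid synthesis, and Gpr37 were at -0.34 ± 0.17 and -0.47 ± 0.26. Astrocyte markers fell, 16 of 19 lower with a mean of -0.21 (camera, adjusted p = 2.42e-05; adjusted p = 0.151 with an estimated correlation). The growth factor receptor Fgfr3 was at -0.34 ± 0.15 and the gap junction gene Gjb6 at -0.40 ± 0.22. Gjb6 was at -0.25 without Aurantiochytrium replicate 1. Without water replicate 2 Gpr37 was at -0.25, Fgfr3 at -0.22 and the astrocyte mean at -0.11, and with array weights it was -0.11 and the oligodendrocyte mean -0.15. In both glial lists 0 genes had an unadjusted p under 0.05 in limma and 0 passed over the list alone. The oligodendrocyte mean was -0.34 and -0.32 with and without poly-A controls, and the astrocyte mean -0.27 and -0.07. The oligodendrocyte scores overlapped between the groups, with water replicate 1 at 0.03 and Aurantiochytrium replicate 2 at 0.04.

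Cortical and amygdalar excitatory neuron markers rose, 18 of 21 higher with a mean of 0.38 (camera, adjusted p = 0.000109; adjusted p = 0.457 with an estimated correlation). Rspo1 (0.72 ± 0.28) was its only member at an unadjusted p under 0.05, Lmo3 was at 0.98 ± 0.50, and 0 passed over the list alone. The water mean of Rspo1, 3.75, lay below the filter level of 3.90, where signal is not shown to be above background. Without water replicate 2 Rspo1 was at 0.41, the mean of the list was 0.27 and its call was lost (adjusted p = 0.111). Choroid plexus markers rose, 7 of 7 higher with a mean of 0.32 (camera, adjusted p = 0.00604; adjusted p = 0.509 with an estimated correlation), with 0 at an unadjusted p under 0.05 and 0 over the list alone. The choroid plexus mean was 0.60 with and -0.26 without poly-A controls. Its call was lost without water replicate 1 (0.17), water replicate 2 (0.23) or Aurantiochytrium replicate 1 (0.24) and by array weights (0.30), and the mean was 0.55 without water replicate 3 and 0.20 without a filter. Circadian clock genes rose, 15 of 17 higher with a mean of 0.19 (camera, adjusted p = 0.0136; adjusted p = 0.509 with an estimated correlation), with Npas2 at 0.95 ± 0.50 and Arntl at 0.45 ± 0.24 (0.14 and 0.065 in their second probe sets), and 0 at an unadjusted p under 0.05 or over the list alone. This call was lost without water replicate 2 (0.11) or Aurantiochytrium replicate 2 (0.11) and with a filter at percentile 60 (0.17). Within batches the cortical mean was 0.47 and 0.20, and the circadian mean 0.23 and 0.11.

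The other 35 lists had adjusted p of 0.0574 to 0.994. Hippocampal granule and pyramidal neuron markers had a mean of 0.24 (adjusted p = 0.0574), and cholesterol biosynthesis genes a mean of -0.15 with 17 of 18 lower (adjusted p = 0.0699, and 0.0462 in camera with the replicate number as a block, where the list was called). In 9 of these 35 lists the mean, the median and the direction of the test did not share a sign. The number of lists called was 18 without Aurantiochytrium replicate 3. Cell division and blood markers, with 2 and 4 tested genes, were not tested as lists.

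Beside Npas4 and Arc, a fixed set of genes of interest for antidepressant treatment was read for Aurantiochytrium against water. The neurotrophin Bdnf was at -0.09 ± 0.30 and the secreted neuropeptide precursor Vgf at 0.09 ± 0.32. Ntrk2, the receptor of Bdnf, was at 0.30 ± 0.19, with probe sets from -0.33 to 0.49. The serotonin receptor Htr1a was at -0.10 ± 0.22, the inhibitor of NF-kappaB Nfkbia at -0.40 ± 0.21, and the glucocorticoid genes Nr3c1, Fkbp5 and Sgk1 at 0.19 ± 0.21, 0.16 ± 0.29 and -0.15 ± 0.99. Camk2a was at 0.36 ± 0.39, Creb1 at -0.01 ± 0.21, the squalene epoxidase Sqle at -0.18 ± 0.19, Gfap at -0.42 ± 0.82 and Neurod1 at 0.12 ± 0.96. Single arrays decided the sign of several of these values. Without water replicate 2 Gfap was at 0.22, Sgk1 at -0.70, Sqle at 0.0037 and Htr1a at 0.0085, and without water replicate 3 Gfap was at -0.90, Sgk1 at 0.24 and Vgf at -0.12. Without Aurantiochytrium replicate 1 Bdnf was at 0.18 and Neurod1 at -0.21, and without Aurantiochytrium replicate 3 Bdnf was at -0.31, Neurod1 at 0.39 and Vgf at 0.40. Creb1 had values of both signs over the arrays left out, and Fkbp5 was at 0.089 without Aurantiochytrium replicate 2. Probe sets of Gfap ranged from -1.21 to -0.42, and those of Bdnf, Fkbp5 and Creb1 differed in sign.

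With imipramine, the genes ranked by unadjusted p against water again included the dopamine transporter and a striatal gene. Slc6a3 was at 4.83 ± 0.62 against 6.15 ± 0.56 in water, a difference of -1.32 ± 0.35, and Rasd2 at 7.67 ± 0.35 against 6.37 ± 0.68, a difference of 1.30 ± 0.40. Rps6ka5, a kinase downstream of MAPK signalling, had the smallest unadjusted p (0.64 ± 0.14, limma unadjusted p = 0.00183). None passed the adjustment: limma called 0 of 10258 genes (smallest adjusted p = 1.00), and 105 genes (39 higher, 66 lower) had an unadjusted p under 0.05 against 512.9 expected by chance. No alternative called a gene in this comparison, array weights included, and the smallest adjusted p over 23 alternatives ranged from 0.105 to 1.00.

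Beside Rps6ka5 and Rasd2, the genes higher on all 3 imipramine arrays with the smallest unadjusted p were Strip2 (1.55 ± 0.36), Tbc1d8 (0.83 ± 0.23), Spata13 (0.92 ± 0.25), Cdc42ep3 (0.66 ± 0.18), Camk4 (0.80 ± 0.22) and Adamts3 (0.91 ± 0.27). On the lower side were Slc6a3, the mannosyltransferase Alg1 (-0.59 ± 0.16), Tanc1 (-0.83 ± 0.24), Eme2 (-0.47 ± 0.14, or -0.35 with the dim imipramine group set at 3.90), the brain metallothionein Mt3 (-0.62 ± 0.19), the copine Cpne6 (-0.78 ± 0.24), Clstn2 (-0.67 ± 0.21) and Sgsm1 (-0.55 ± 0.17). A second probe set gave 0.51 for Rasd2 and 0.39 for Cdc42ep3, and 1 of 3 gave 0.49 for Camk4. Of the 26 named genes with several probe sets above the filter, 16 had one that differed by more than 1.5 times and 5 one of the other sign. Groups did not overlap for 3.11% of genes, against a chance share of 10%. At an unadjusted p under 0.05 and at least 1.5-fold, 38 genes differed (19 higher, 19 lower). This count was 130 (93 higher, 37 lower) without imipramine replicate 2, 119 without imipramine replicate 1, 186 without imipramine replicate 3 and 62 without water replicate 3. It was 47 with the poly-A control batch as a block and 83 within the 6 arrays with these controls. Without imipramine replicate 2, limma called 0 genes with 248 at an unadjusted p under 0.05 (smallest adjusted p = 0.982).

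For imipramine against water, 8 of 46 lists were called by camera (3 higher, 5 lower), and 0 by camera with an estimated correlation (1 list at unadjusted p under 0.05, smallest adjusted p 0.578) or by fry (0 lists at unadjusted p under 0.05, smallest adjusted p 0.734). The count was 4 without water replicate 2, 5 without water replicate 3, and 10 without imipramine replicate 2, of which 4 were among the 8 with the same direction and 1 with the opposite one. Striatal medium spiny neuron markers rose, 15 of 15 higher with a mean of 0.79 (camera, adjusted p = 1.36e-14; adjusted p = 0.578 with an estimated correlation). Rasd2, Scn4b (0.91 ± 0.29), Ppp1r1b (1.60 ± 0.56) and Adcy5 (0.66 ± 0.27) had an unadjusted p under 0.05, with 0 passing over the list alone. Scn4b was at 0.58 without water replicate 1. The mean of the list was 0.49 without imipramine replicate 1, 0.50 without imipramine replicate 3 and 1.38 without imipramine replicate 2, the array with the Gapdh ratio of 7.55. In that last fit 11 genes passed over the list alone. With array weights the mean was 1.41, with the RNA quality covariate on 8 arrays 1.24, and within batches 0.79 and 0.80.

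Markers of midbrain dopamine and hindbrain serotonin neurons fell with imipramine, 8 of 9 lower with a mean of -0.58 (camera, adjusted p = 0.00476; adjusted p = 0.804 with an estimated correlation). Slc6a3, Aldh1a1 (-0.93 ± 0.34) and the transcription factor Nr4a2 (-0.48 ± 0.19) had an unadjusted p under 0.05, 1 gene passed over the list alone, and Ddc was at -1.26 ± 0.58 (-0.74 without water replicate 2 or imipramine replicate 1). The call was lost without water replicate 2 (-0.30), imipramine replicate 1 (-0.31) or imipramine replicate 3 (-0.47), and the mean was -0.97 without imipramine replicate 2, -0.90 with array weights and -0.31 without a filter. Within the arrays with poly-A controls it was -0.61 (adjusted p = 0.0921), without them -0.53, and with the batch as a block the adjusted p was 0.0200.

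The other 6 calls for imipramine had an adjusted p of 0.0374 each (adjusted p = 0.804 with an estimated correlation for each), and in each of these lists 0 genes passed over the list alone. Oligodendrocyte markers fell, 16 of 17 lower with a mean of -0.27, among them Ndrg1 at -0.55 ± 0.26 and the transferrin gene Trf at -0.57 ± 0.37, with 0 genes at an unadjusted p under 0.05 in limma. These genes were at -0.23 and -0.20 without imipramine replicate 2. The oligodendrocyte mean was -0.45 with and 0.07 without poly-A controls, the call was lost without water replicate 2 (-0.17) or imipramine replicate 1 (-0.17) and with a filter at percentile 60 (-0.28), and the mean was -0.43 without imipramine replicate 3. Ribosomal protein genes fell, 37 of 42 lower with a mean of -0.23 and 0 at an unadjusted p under 0.05. That list was called in the opposite direction without imipramine replicate 2 (0.088, adjusted p = 0.0242), was at -0.47 without imipramine replicate 3, lost its call without water replicate 1 (-0.26) or water replicate 3 (-0.16), and lay at -0.40 and 0.10 within batches. The ribosomal call was also lost with the RNA quality covariate, which is the log2 Gapdh ratio (-0.03, adjusted p = 0.961; on 8 arrays -0.04, adjusted p = 0.810), with array weights (-0.04) and with a filter at percentile 60 (-0.24).

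Cerebellar neuron markers, a list of a region outside the limbic area, rose with 5 of 7 higher and a mean of 0.36, with the glutamate receptor Grm4 at 0.85 ± 0.64, Neurod1 at 0.87 ± 0.96 and 0 at an unadjusted p under 0.05. Grm4 was at -0.03 and Neurod1 at -0.44 without imipramine replicate 2. The cerebellar mean was -0.14 without imipramine replicate 2 (adjusted p = 0.616), 0.58 without imipramine replicate 1 and 0.64 without imipramine replicate 3, the call was also lost without water replicate 2 (0.41) or water replicate 3 (0.34), and within batches the mean was 0.61 and -0.15. It was also lost with the RNA quality covariate (0.09; on 8 arrays -0.10), array weights (-0.06), quantile normalisation (0.41), averaged probe sets (0.42), a filter at percentile 60 (0.38) and the replicate number as a block (camera, adjusted p = 0.0537), and the mean was 0.60 without a filter. Heat shock and unfolded protein response genes fell, 20 of 26 lower with a mean of -0.21, including the chaperone genes Dnajb1 (-0.40 ± 0.21) and Hspe1 (-0.65 ± 0.35, and -0.39 without imipramine replicate 2), with 0 at an unadjusted p under 0.05. Dnajb1 was at -0.26 without imipramine replicate 1. Their call was lost without water replicate 2 (-0.15), water replicate 3 (-0.19), imipramine replicate 1 (-0.19) or imipramine replicate 2 (-0.11), the mean was -0.33 without imipramine replicate 3, and within batches it was -0.31 and -0.0034. That call was also lost with the RNA quality covariate (-0.14; on 8 arrays -0.16), array weights (-0.16) and a filter at percentile 60 (-0.24).

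Glucocorticoid response and stress axis genes fell with imipramine, 15 of 19 lower with a mean of -0.27. The stress-induced inhibitor of mTOR signalling Ddit4 (-0.78 ± 0.30) and the corticotropin-releasing hormone binding protein Crhbp (-0.50 ± 0.20) had an unadjusted p under 0.05, and the glucocorticoid-induced Tsc22d3 was at -0.41 ± 0.19. Ddit4 was at -0.52 and Crhbp at -0.32 without imipramine replicate 2, and Tsc22d3 at -0.26 without imipramine replicate 1 and at -0.85 in a second probe set. The call was lost without water replicate 1 (-0.25), water replicate 3 (-0.27), imipramine replicate 1 (-0.34), imipramine replicate 2 (-0.12) or imipramine replicate 3 (-0.37), and within batches the mean was -0.37 and -0.09. It was also lost with the RNA quality covariate (-0.20, adjusted p = 0.0695; on 8 arrays -0.10, adjusted p = 0.425), array weights (-0.16), averaged probe sets (-0.24) and a filter at percentile 60 (-0.28). The list of cAMP, CREB and MAPK genes was called higher by camera with 11 of 26 genes higher, a mean of 0.04 and a median of -0.05, so that mean and median differed in sign. Without Adcy5 and Pde10a, which the striatal list also holds, the mean was 0.0042. Camk4, Rps6ka3 (0.46 ± 0.17) and Adcy5 were its 3 members at an unadjusted p under 0.05. Its call was lost without water replicate 2 (0.02), water replicate 3 (0.08), imipramine replicate 1 (-0.10) or imipramine replicate 3 (-0.02), without a filter (0.04) and with the replicate number as a block (camera, adjusted p = 0.0840). The mean was 0.26 without imipramine replicate 2, 0.29 with array weights, 0.15 with the RNA quality covariate (0.26 on 8 arrays), 0.09 with quantile normalisation and 0.03 with median centring, and within batches it was 0.01 and 0.11. The other 38 lists had adjusted p of 0.0540 to 0.975, and in 8 of them mean, median and test did not share a sign.

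The values of several genes of interest had another sign or size without imipramine replicate 2. Fos was at -0.67 ± 0.97 with imipramine and at 0.54 without that array, Sgk1 at -0.86 ± 0.99 and 0.44, and Neurod1 at 0.87 ± 0.96 and -0.44. Bdnf was at -0.28 ± 0.30 and -0.05, Htr1a at -0.44 ± 0.22 and -0.24, Camk2a at -0.54 ± 0.39 and -0.02, and Ntrk2 at -0.07 ± 0.19 and 0.12. Nr3c1 was at -0.25 ± 0.21 and 0.01, Arc at -0.27 ± 0.61 and 0.43, and Npas4 at 0.10 ± 0.38 and 0.44. Probe sets of Htr1a (-0.44 and 0.01), Ntrk2 (-0.69 to 0.15) and Nr3c1 (-0.25 to 0.24) differed in sign, and those of Bdnf ranged from -0.28 to -0.08 and of Camk2a from -1.02 to -0.54.

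**Figure D3:**
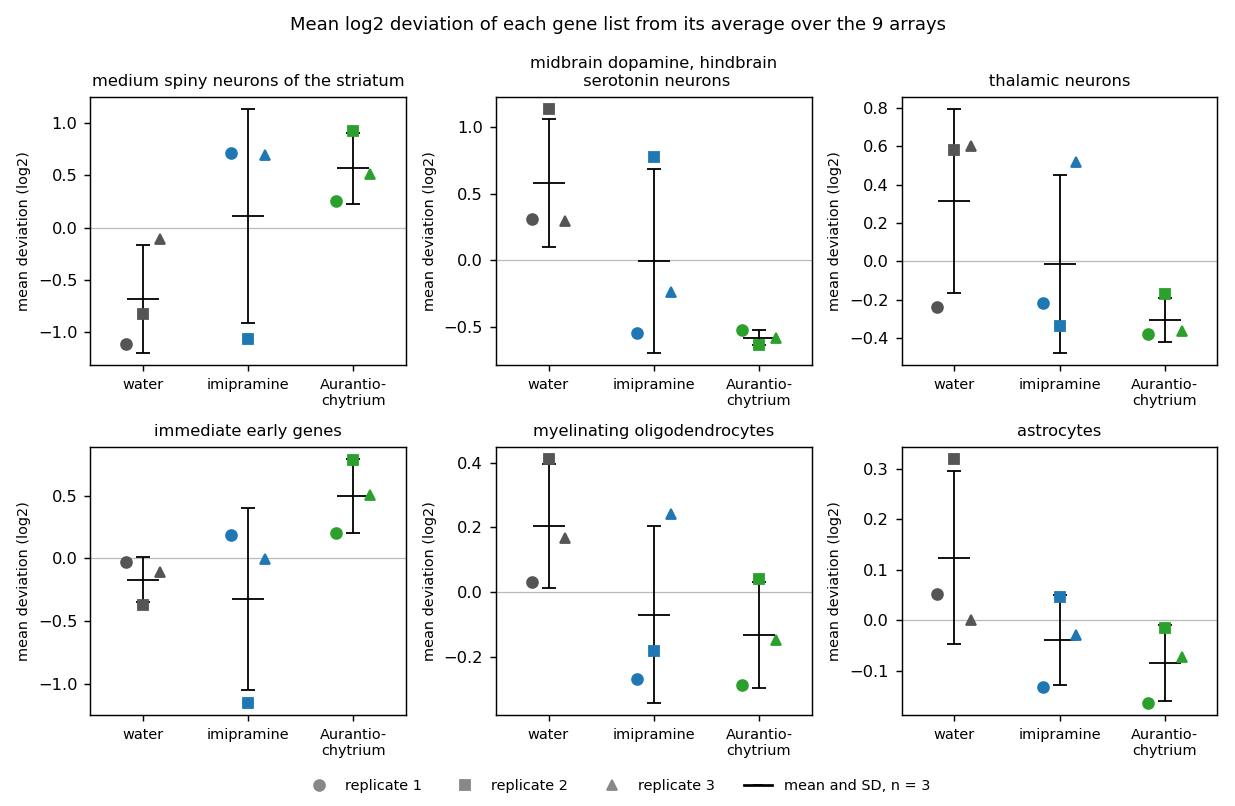
Mean log2 deviation of 6 gene lists from their average over the 9 arrays, with points for arrays, symbols for replicate numbers and lines for the mean and SD of 3 arrays per group. The striatal score was -0.68 ± 0.52 with water, 0.11 ± 1.02 with imipramine and 0.56 ± 0.34 with Aurantiochytrium, and the score of imipramine replicate 2 was -1.06.

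The direct comparison of the treatments asks where Aurantiochytrium differed from the positive control. Fosb, a transcription factor gene of the immediate early list, was at 5.18 ± 0.30 with Aurantiochytrium against 4.21 ± 0.09 with imipramine, a difference of 0.97 ± 0.20. Npas4 differed by 1.39 ± 0.38, and on the lower side Slc6a3 by -1.05 ± 0.35 (-0.93 with the dim Aurantiochytrium group set at 3.90) and Aldh1a1 by -0.87 ± 0.34. These 4 differences were 0.92, 1.05, -0.72 and -0.45 without imipramine replicate 2. Limma called 0 of 10258 genes (smallest adjusted p = 0.992), with 114 genes (105 higher, 9 lower) at an unadjusted p under 0.05 against 512.9 expected by chance, and no alternative called a gene.

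The other genes of the ranking were Alg1 (0.63 ± 0.16), Ddit4l (0.75 ± 0.21) and the lysosomal mannosidase Man2b1 (0.51 ± 0.15) on the higher side, and 4632427E13Rik (-0.61 ± 0.22), Ap4m1 (-0.35 ± 0.14) and the synaptic vesicle priming gene Unc13c (-0.45 ± 0.18) on the lower side. Groups did not overlap for 3.94% of genes, against a chance share of 10%. At an unadjusted p under 0.05 and at least 1.5-fold, 53 genes differed (49 higher, 4 lower). The count was 33 without imipramine replicate 2, 260 without imipramine replicate 1, 191 without imipramine replicate 3, 35 without water replicate 3 and 15 without Aurantiochytrium replicate 2. It was 56 with the poly-A control batch as a block and 63 within the arrays with these controls. Without imipramine replicate 2, limma called 0 genes with 96 at an unadjusted p under 0.05.

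Against imipramine, 7 of 46 lists were called by camera (3 higher, 4 lower), and 0 by camera with an estimated correlation (2 lists at unadjusted p under 0.05, smallest adjusted p 0.723) or by fry (1 list at unadjusted p under 0.05, smallest adjusted p 0.645). The count was 12 without imipramine replicate 1 and 11 without Aurantiochytrium replicate 3. Immediate early genes rose, 23 of 23 higher with a mean of 0.82 (camera, adjusted p = 8.72e-14; adjusted p = 0.751 with an estimated correlation), with 6 at an unadjusted p under 0.05 and 1 passing over the list alone. That mean was 0.41 without imipramine replicate 2, 0.50 with the RNA quality covariate on 8 arrays, and 0.98 and 0.52 within batches. Cortical and amygdalar neuron markers rose, 18 of 21 higher with a mean of 0.69 (camera, adjusted p = 1.27e-05; adjusted p = 0.751 with an estimated correlation), which was 0.26 without imipramine replicate 2, 0.25 with the RNA quality covariate on 8 arrays, 0.21 with the call lost under array weights, and 0.87 and 0.33 within batches. Hippocampal neuron markers rose, 10 of 13 higher with a mean of 0.54 (camera, adjusted p = 0.0236; adjusted p = 0.825 with an estimated correlation), and lost the call without imipramine replicate 2 (0.14), imipramine replicate 3 (0.72) or Aurantiochytrium replicate 1 (0.55). The hippocampal call was also lost with array weights (0.15) and with the RNA quality covariate on 8 arrays (0.15), and the mean was 0.34 with that covariate on 9 arrays and 0.73 and 0.16 within batches.

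Midbrain and hindbrain monoamine neuron markers fell against imipramine, 8 of 9 lower with a mean of -0.58 (camera, adjusted p = 1.05e-05; adjusted p = 0.751 with an estimated correlation), at -0.19 without imipramine replicate 2, -0.14 with array weights, -0.36 with the RNA quality covariate (-0.30 on 8 arrays) and at -0.69 and -0.35 within batches. Monoamine metabolism genes fell, 8 of 9 lower with a mean of -0.47 (camera, adjusted p = 0.000112; adjusted p = 0.723 with an estimated correlation), at -0.24 without imipramine replicate 2, -0.12 with array weights, -0.26 with the RNA quality covariate on 8 arrays, -0.71 without imipramine replicate 1 and at -0.50 and -0.40 within batches. Without Th, Ddc and Slc6a3, which both lists hold, the midbrain mean was -0.28 and the monoamine mean -0.12. Thalamic markers fell, 12 of 14 lower with a mean of -0.29 (camera, adjusted p = 0.000268; adjusted p = 0.751 with an estimated correlation). The thalamic call was lost without imipramine replicate 3 (-0.03), with array weights (-0.11) and within the arrays with poly-A controls (0.0038, adjusted p = 0.395), the pair without them differed by -0.88, and the mean was -0.45 without imipramine replicate 2. Cerebellar markers fell, 7 of 7 lower with a mean of -0.50 (camera, adjusted p = 0.00241; adjusted p = 0.751 with an estimated correlation), at -0.0031 with the call lost without imipramine replicate 2, -0.78 without imipramine replicate 3, and -0.75 and -0.01 within batches. The cerebellar call was also lost with array weights (-0.06) and with the RNA quality covariate on 8 arrays (-0.05), and the mean was -0.24 with that covariate on 9 arrays. Apart from the 1 immediate early gene, 0 genes of these 7 lists passed over the list alone and 0 over all genes. Striatal markers had a mean of 0.45 (adjusted p = 0.263), which was -0.14 without imipramine replicate 2. The other 39 lists had adjusted p of 0.0581 to 0.964, and in 10 of them mean, median and test did not share a sign.

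The log2 differences from water were compared between the treatments over 10258 genes, which are not independent replicates. The covariance was 0.0169 and Pearson's r 0.304, against 0.0650 and 0.499 on average in 100 simulations of unchanged groups that share the water arrays. Without imipramine replicate 2 the covariance was 0.0342 and r 0.620, against 0.0284 (highest 0.0318) and 0.450. These simulations treat arrays as independent. In 100 more, where arrays of equal replicate number shared part of their noise, the covariance was 0.0453 over 9 arrays and 0.0157 over 8, and r 0.498 and 0.414. All these simulations use 1 residual spread per gene for every array. Over 9 arrays the spread of imipramine replicate 2 thus falls on the simulated water arrays too, which raises the simulated covariance. The 9-array values therefore cannot show that the treatments agree less than unchanged groups would. The observed covariance was 0.0417 without water replicate 2, 0.0312 without water replicate 3 and 0.000903 without Aurantiochytrium replicate 1. Both treatments shared the sign of the difference in 59.3% of genes, against 66.7% in the simulations, and in 65.6% against 64.8% without imipramine replicate 2. Of the genes at an unadjusted p under 0.05 and at least 1.5-fold, 15 were among both the 19 higher with imipramine and the 50 higher with Aurantiochytrium, where independent lists would share 0.0926, and 6 among both the 19 and the 24 lower, where they would share 0.0445. The unchanged groups of the simulations, whose lists were longer at 147 and 148 genes higher on average, shared 34.7 higher and 35.6 lower. As a share of the imipramine list this was 78.9% against 23.7% in simulations on the higher side and 31.6% against 24.3% on the lower. Without imipramine replicate 2, 69 of the 93 higher genes were shared (74.2%, against 17.0% in simulations), where independent lists would share 1.20, and 14 of the 37 lower ones (37.8% against 17.3%), where they would share 0.151. With noise shared by replicate number, the simulated shares were 22.7% higher and 23.0% lower over 9 arrays, and 15% and 14.0% over 8. Independent lists leave out the shared water arrays and the simulations leave out any effects. The simulations set noise gene by gene and hold no term for genes that vary together. Striatal markers did so within groups, at a mean correlation of 0.353 over the 8 arrays. The simulated values may therefore understate how far covariance and overlap can range in unchanged groups. The 3 water arrays cannot be split into parts of 2, so part of the overlap may come from the shared controls.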

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

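The tests of the regional lists and of imipramine replicate 2 were chosen only after the result was seen, as was the test of the immediate early genes with the midbrain score, while their tests with the striatal score and the Gapdh ratio and the tests of the other splits were written before. The control transcripts outside the gene comparisons singled out imipramine replicate 2. Its poly-A control intensities were 462 for Dap, 106 for Thr, 43.9 for Phe and 35.6 for Lys, where the highest water array had 118, 14.2, 11.7 and 8.46. Its Gapdh 3' over 5' ratio of 7.55 and Actb ratio of 6.16 compare with at most 1.86 and 2.69 in water.

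Imipramine replicate 2 stood apart from the other 8 arrays, with a median correlation to them of 0.914, and with 29.6% of genes above and 37.4% below every other array. Degraded RNA may account for this: its Gapdh ratio of 7.55 lay above the highest other value of 2.19, and in the other 8 arrays the main axis of variation followed the same ratio. Tissue from the cerebellum is a second candidate explanation, since the median deviation of the cerebellar markers on this array was 1.13 against 0.42 at the 95th percentile of matched random lists, and 6 of 7 markers lay above every other array. The score of this array was 1.29 for cerebellar markers, against at most 0.02 on the others. It was -1.20 for cortical and amygdalar and -1.09 for hippocampal markers, against at least -0.26 and -0.10. Its striatal (-1.06) and midbrain (0.77) scores lay within the range of the others. That 6 of 7 cerebellar markers exceeded every other array, against 29.6% of genes, argues against degraded RNA as the only cause. Degraded RNA as a part and cerebellar tissue stay open and can hold together. A mislabelled or mixed sample was not tested. No biological explanation was tested, as the design gives none for a single array.

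Striatal markers were higher and midbrain markers lower with both treatments than with water. Degraded RNA on imipramine replicate 2 is argued against as the cause, because the striatal shift with imipramine was 1.38 without that array and 0.79 with it. Unequal shares of neighbouring regions in the dissected tissue stay open: the striatal markers varied together within groups at a mean correlation of 0.353 against 0.199 at the 95th percentile of matched random lists, and the midbrain (0.447) and thalamic (0.449) lists did likewise. Immediate early genes, which are not a regional list, did so too (0.319 against 0.142). The measure therefore cannot tell shares of tissue from other shared variation. It shows variation between samples of a group, not a difference between the groups. An effect of the treatments stays open too. The lowest treated score minus the highest water score was -0.96 over 9 arrays and 0.36 without imipramine replicate 2, so that this single array decides whether the scores overlap. Dissections that differ between the groups would also separate the scores, so this gap cannot tell them from an effect of the treatments.

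Immediate early genes were higher with Aurantiochytrium than with water. RNA quality is argued against, since the shift over the 8 arrays without imipramine replicate 2 was 0.68 ± 0.17 (SE) with the log2 Gapdh ratio as a covariate and 0.67 ± 0.18 without it. Unequal shares of regions stay open: with the striatal score as a covariate the shift was 0.35 ± 0.37, and with the midbrain score 0.16 ± 0.35, where both covariates differ between the groups and so widen the error. An effect of the treatment, or differences in handling or time of day before sampling, may also have raised these genes and were not tested.

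Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. Limma called 0 genes in the real split of each comparison and at most 0 in the others, so that all 10 splits gave as many. Of genes at an unadjusted p under 0.05 and at least 1.5-fold, the real splits gave 38, 74 and 53 for imipramine against water, Aurantiochytrium against water and Aurantiochytrium against imipramine, with the highest other split at 1481, 163 and 1295, and 7, 3 and 6 of the 10 splits gave as many as the real ones. For lists called by camera the real values were 8, 11 and 7 and the highest others 8, 13 and 15, with 2, 3 and 5 of 10 splits as large. If the replicate numbers pair the arrays, which is not established, 4 splits part all 3 pairs, as the real one does, and the other 6 splits part 1 pair. Among those 4, the highest other gave 31 genes against 38 for imipramine against water and 10 against 74 for Aurantiochytrium against water. The lists called were 7 against 8 and 13 against 11. For Aurantiochytrium against imipramine the highest other exceeded the real split, with 117 genes against 53 and 12 lists against 7. Splits that give many times the real count point to a structure of the samples: in each comparison the split with the highest count set the 3 arrays of highest Gapdh ratio against the 3 of lowest. With the log2 Gapdh ratio as a covariate, the real comparisons gave 98, 213 and 76 genes.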

How the results depend on the processing

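These alternatives were chosen after seeing the data: the RNA quality covariate on 9 and on 8 arrays, the poly-A control batch as a block, and the 6 arrays with these controls. In what follows, the smaller-p count is the number of genes at an unadjusted p under 0.05 and at least 1.5-fold. Of the alternative values of the main counts and of the covariance, 194 stayed within 1.5 times or within the spread and 42 moved. Genes called stayed at 0 in limma under 23 of 23, 22 of 23 and 23 of 23 alternatives (smaller-p counts 38, 74 and 53), except for 3 genes with array weights in Aurantiochytrium against water. For imipramine against water the smaller-p count was 190 with array weights, 98 with the RNA quality covariate, 109 with that covariate on 8 arrays and 83 with only the poly-A control arrays, and leaving out an array gave 33 to 186. For Aurantiochytrium against water it was 352 with array weights, 169 with only the 2 groups, and 213 with the RNA quality covariate on 9 arrays and 213 on 8, with 37 to 174 on leaving out an array. For Aurantiochytrium against imipramine it was 300 with array weights and 25 with only the 2 groups, with 15 to 260 on leaving out an array. Lists called fell from 8, 11 and 7 to 0, 0 and 0 with an estimated correlation and to 0, 0 and 0 with fry. For imipramine against water 2 were called with the filter at percentile 60, and 4 to 10 on leaving out an array. Leaving out an array gave 8 to 18 for Aurantiochytrium against water. Against imipramine, 16 were called without a filter, 4 with array weights, 12 with only the poly-A control arrays, and 7 to 12 on leaving out an array. The covariance between treatments ranged from 0.000903 to 0.0417 on leaving out an array. Ribosomal proteins for imipramine against water reversed from -0.23 to 0.088 without imipramine replicate 2, with -0.47 to 0.088 on leaving out an array. The cause was not tested for any of these shifts. Over single lists, 119 alternative values lost a call, 136 gained one and 3164 kept their side of the threshold. Of the called lists, 1 of 8, 8 of 11 and 3 of 7 kept their call under all 23 alternatives other than estimated correlation and fry. Of the named genes' values, 3089 kept their side, 3 gained a call and 78 uncalled ones changed sign. Quantile normalisation and median centring moved the median log2 difference to between -0.07 and 0.07.

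For Aurantiochytrium against imipramine, equal replicate numbers were not taken as pairs, since 1 of 3 pairs had deviations correlated above 0.1 (0.784 for replicate 3, -0.43 and -0.14 for the others). Over the 3 groups, 6 of 9 arrays matched best the array of their own number. This cannot tell pairing from batch or RNA quality. The replicate 3 arrays lacked poly-A control signal and had the lowest Gapdh ratios (0.944 to 1.04), and their deviations were correlated at 0.780 to 0.791. Water and imipramine replicates 2, correlated at 0.752, had the highest Gapdh ratios of their groups (1.86 and 7.55). With the replicate number as a block, the smaller-p counts were 57, 101 and 73 and the lists called 6, 12 and 7. Apart from the loss of the cAMP, CREB and MAPK and the cerebellar calls for imipramine against water and the gain of cholesterol biosynthesis for Aurantiochytrium against water, the block changed no list or named gene's call. On leaving out an array, the log2 difference of 38 of 60, 28 of 66 and 1 of 10 named genes moved by more than 1.5 times or changed sign. Genes far below the filter intensity of 14.9 lie too close to background to be compared here, and in simulation for imipramine against water 45% of genes changed by a log2 of 1 were recovered. That simulation drew independent noise of equal spread on all arrays. The real fit had 105 genes at an unadjusted p under 0.05 against 512.9 expected by chance, so its recovery may be lower.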

Other observations

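The tests of single hypothalamic peptides were chosen only after their values were seen. Pmch, which encodes melanin-concentrating hormone of lateral hypothalamic neurons, had log2 intensities of 8.04 ± 0.11 (SD, n = 3) in water, 6.06 ± 3.30 with imipramine and 5.47 ± 1.36 with Aurantiochytrium. The single imipramine arrays were at 7.57, 2.28 and 8.34, with replicate 2 at 2.28, and the Aurantiochytrium arrays at 6.82, 5.49 and 4.10. Hcrt, the orexin precursor of the same area, was at 5.28 ± 0.20, 4.57 ± 0.65 and 4.12 ± 0.64. For Aurantiochytrium against water Pmch differed by -2.57 ± 1.44 (limma, unadjusted p = 0.111) and Hcrt by -1.16 ± 0.39 (unadjusted p = 0.0167, adjusted p = 1.00), so neither passed. Other peptides of the same list went the other way. Oxt was at 5.82 ± 0.17 in water, 6.34 ± 0.56 with imipramine and 6.36 ± 0.54 with Aurantiochytrium, and Avp at 4.61 ± 0.55, 5.55 ± 1.28 and 5.46 ± 0.96. The hypothalamic list as a whole was not called in any of the 3 comparisons.

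Lists of other brain processes gave values without a call. Cholesterol efflux, neuroinflammation and interferon-stimulated genes had mean log2 differences for imipramine against water of 0.03, -0.03 and -0.05, and of 0.01, 0.03 and -0.14 without imipramine replicate 2, the array with the Gapdh ratio of 7.55. Synaptic vesicle genes were at -0.22, with 20 of 26 lower, and at -0.16 without that array. Proteasome genes were at -0.30, with 24 of 29 lower, and at 0.09 without it, so that this array sets the sign.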
